A study of Saccharomyces cerevisiae with 30 samples.

How the data were processed

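The deposited tables held, for each of 30 libraries, 1 footprint count and 1 RPKM value per gene over 5890 listed genes, per the file headers. Counts are numbers of aligned ribosome footprints per gene as made by the authors. RPKM values are the authors' counts scaled by gene length and by a library total, per the file headers, and were used only to compare the listed counts with the total behind the scaling. Per the submitters' processing notes, reads were handled with CASAVA (version not given), Bowtie 1.1.2 and TopHat2 2.1.1 on the yeast build sacCer3. Whether molecular identifiers were collapsed, whether counts were kept by strand, and how reads with several matches were treated are not given in the sources used here. Counts of near-identical paralogs (HXT6 and HXT7, TDH2 and TDH3, SSA1 and SSA2, TEF1 and TEF2, the ENA genes and most ribosomal protein pairs) and of overlapping or antisense genes are therefore uncertain. No value was given in the RPKM column for 119 genes, which had 0 counts. A reference table named 5887 of the listed genes, and its symbols were used for 169 genes where the deposited tables had another name.

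Each library belonged to a pair of an input and a streptavidin pulldown from the same culture, 15 pairs in all, and pairs were grouped by the labels into 5 series of 1 biotin ligase and 1 cycloheximide condition. Each combination of series, auxin time and fraction had 1 library, so the unit that repeats is the series. P-values therefore measure consistency over series and not over replicate cultures, except in the bait and cycloheximide comparisons. Each of those sets 1 series against 1 other, and its p-values measure consistency over matched auxin times. They cannot part the bait or the drug from other differences between both series. Genes with a mean input count of at least 20 were tested, 5286 genes. Enrichment is the log2 ratio of pulldown to input in a pair, after TMM scaling with a prior count of 1. Library totals of the listed genes ran from 2.04 M to 113 M counts in inputs (median 22.0 M) and from 4.86 M to 103 M in pulldowns (median 19.7 M).

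Counts were fitted with the edgeR 4.0.16 quasi-likelihood test in R 4.3.3, 2-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Pairs were a block and the interaction of fraction with each condition gave the enrichment coefficients. The comparison of baits without auxin used 10 libraries and left 3 residual degrees of freedom. A joint model of 30 libraries, with a separate enrichment for each series, gave the changes at ER baits after 15, 30 and 60 min and at mitochondrial baits after 30 min, and the difference of both 30 min changes, with 6 residual degrees of freedom. The comparison of both ER baits used 16 libraries (3 degrees of freedom) and that of cycloheximide 12 libraries (2 degrees of freedom), each with the auxin time as a block. Input changes were fitted on the 15 inputs with the series as a block (7 degrees of freedom). Fitted values are given as log2 change ± standard error (SE) with the adjusted p of edgeR, and n is the number of series or matched times. Spreads of list medians over series are standard deviations (SD).

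Comparisons, tests, thresholds, gene lists, alternatives and the rule for naming genes were fixed before the data were examined. The rule named up to 10 genes in each direction with the largest change among those past the threshold that changed the same way in every series, up to 3 members of each list that bears on a comparison, the 5 genes with the smallest p where fewer than 5 passed, and as fixed examples DAP2, PHO8, KAR2, PRC1, GAS1, PDI1, SUC2 and the genes of SRP and its receptor. Examples in the text come from these genes.

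The 25 lists were SRP and its receptor, the Sec61 and Ssh1 translocons with the Sec63 complex, the GET and SND pathways, soluble proteins with a signal sequence, GPI-anchored proteins, single-pass signal-anchor glycosyltransferases and proteases, plasma membrane transporters, polytopic ER proteins, tail-anchored proteins of the secretory pathway, mitochondrial matrix and inner membrane proteins with a presequence, mitochondrial carriers, outer membrane proteins, mitochondrial ribosomal proteins, mitochondrial import receptors and translocases, cytosolic ribosomal proteins, glycolysis, translation factors, the proteasome, Hsf1 heat-shock genes, unfolded protein response genes, general stress genes, mitochondrial import stress genes, ribosome biogenesis, peroxisomal proteins, and chromatin and nuclear proteins. Some lists were filled by name patterns, and these also took in RPP1 (RNase P) among cytosolic ribosomal proteins, MRP8 (function unknown) among mitochondrial ribosomal proteins, and the transcription factor RPN4 and the assembly chaperone RPN14 in the proteasome list. The lists were kept as fixed, and counts without these genes were made after the results were seen and differed by at most 3 genes. The GPI-anchored list also held PGA1, a subunit of a GPI-synthesis enzyme. The polytopic ER list also held single-pass proteins, among them OST1, WBP1, GPI8, EMP24 and ERV25, which have a cleaved signal sequence. The import stress list also held genes of the drug-resistance regulators Pdr1 and Pdr3. No counts were made without these members. Lists were tested with limma 3.58.1, by camera with a preset correlation of 0.01, by camera with an estimated correlation, and by fry. Camera compares a list with the other genes. Fry tests whether a list moves one way on balance, its mixed form whether members change in either direction, and neither compares a list with other genes. An ER set was defined as the genes with a log2 enrichment of at least 1 in the Ubc6 pair at 0 min, and its change was read in the Sec63 series, so that the libraries that define the set do not measure its change. For mitochondrial baits the set was the genes with a mean of at least 1 over the 3 ER pairs at 0 min.

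Alternatives tried were no filter on low genes, a mean input count of at least 50, library totals without TMM, centring each pair on glycolysis and translation factor genes, DESeq2 1.42.0, no series block, separate fits for ER and mitochondrial series, other limits for the ER set, and leaving out each series or time. Centring on each pair's median, library totals for the inputs, and TMM against another reference library were added after the data were seen. Pseudocount alternatives do not apply to counts beyond the prior count. Classes of targeting signal were planned from translated reading frames but were not run, as no genome sequence was used here. TMM scales every library to 1 reference library, and edgeR chose the Ubc6 pulldown at 60 min as that reference in the joint model. Without a filter, or at a mean input count of at least 50, it chose the Tom20 pulldown at 30 min.

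The models were run on simulated counts in which 200 of the 5286 genes were changed by known folds. At 2-fold, edgeR recovered 53.7% of the changed genes for the ER change after 30 min, 55.2% after 60 min and 59.7% after 15 min. It recovered 55.2% for the mitochondrial change, 22.4% for the difference of the changes, 70.1% for the bait and 55.2% for cycloheximide. For each of the input changes after 30 and 60 min it recovered 95.5%. At 4-fold these shares were 97.0%, 95.5%, 86.4%, 95.5%, 72.7%, 97.0%, 98.5% and 98.5%. The input change after 15 min was not simulated. The comparison of baits without auxin recovered 0% at 2-fold, 50.7% at 4-fold and 92.4% at 16-fold. False calls were 2 to 15 of 5086 unchanged genes and at most 12.1% of all calls, in the cycloheximide comparison. The changed genes were few and went up and down in about equal numbers. Errors of scaling that arise when many genes change, or change mostly one way, were therefore not simulated. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.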

Results

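Proximity-specific ribosome profiling was measured in budding yeast in which Srp72, a core protein of the signal recognition particle (SRP), carried an auxin-inducible degron. SRP binds ribosomes that translate secretory and membrane proteins and brings them to the endoplasmic reticulum (ER). Auxin at 500 µM starts degradation of the tagged protein, and cells were collected after 0, 15, 30 or 60 min. A biotin ligase (BirA) fixed to 1 cell surface biotinylates passing ribosomes that carry an acceptor tag on Rpl16, and a streptavidin pulldown collects them. Footprints of the pulldown and of the whole-cell input were sequenced, and their ratio, the enrichment, shows which messages are translated near that surface. The ligase was on Sec63 (beside the translocon), on Ubc6 (a tail-anchored ER protein), on Tom20 or on Om45 (both on the mitochondrial outer membrane).

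The 30 libraries made 15 pairs of input and pulldown in 5 series. The Sec63 series with cycloheximide and the Ubc6 series each had 4 auxin times (0, 15, 30 and 60 min). The Sec63 series without cycloheximide had 3 times (0, 30 and 60 min), and the Tom20 and Om45 series had 2 times each (0 and 30 min). Cycloheximide, which stops elongation, was given at 100 µg/ml for 2 min together with a 2 min biotin pulse, whereas the series without it had a 1 min pulse. No condition had a replicate library. The Tom20 strain was W303 and the others were S288C derivatives, so the bait and the strain differ together in that series. Footprints in listed genes totalled 2.04 M to 113 M per input and 4.86 M to 103 M per pulldown. Coordinates refer to sacCer3.

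The first comparison asked which messages were translated at each surface while SRP was present, with 3 ER pairs set against 2 mitochondrial pairs at 0 min. Secretory messages were enriched at ER baits and messages of mitochondrial proteins at mitochondrial baits. The gene of the cell-wall anchor Aga1 (YNR044W, chromosome XIV, 703699 to 705876) was 4.62 ± 0.67 log2 units (SE) higher at the ER (edgeR adjusted p = 0.00685). KAR2, which encodes the ER Hsp70, was 3.60 ± 0.70 higher (adjusted p = 0.0196), SEC61 3.52 ± 0.74 higher (adjusted p = 0.0244) and DAP2, a vacuolar dipeptidase, 3.68 ± 0.71 higher (adjusted p = 0.019). The message of the import receptor TOM70 (YNL121C, chromosome XIV, 398684 to 400537) was 3.95 ± 0.32 log2 units lower at the ER than at mitochondria, a value of −3.95 (adjusted p = 0.00154). ATP2, a subunit of the ATP synthase, had −4.33 ± 0.48 (adjusted p = 0.00271) and MIS1, a matrix enzyme, −4.85 ± 0.61 (adjusted p = 0.00397). PRC1, the vacuolar carboxypeptidase, did not pass at 3.12 ± 0.88 (adjusted p = 0.0558), nor did SUC2 at 1.09 ± 0.36 (adjusted p = 0.0896).

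By list, 20 of 36 soluble proteins with a signal sequence, 18 of 36 GPI-anchored proteins, 32 of 34 single-pass signal-anchor proteins, 32 of 78 plasma membrane transporters and 66 of 93 polytopic ER proteins were higher at the ER, and none of their members were higher at mitochondria. Adjusted over the list alone, the counts were 29, 22, 33, 68 and 85. The unfolded protein response genes, many of which encode ER proteins, had 18 of 31 higher, and the translocon list had 3 of 9 higher, among them SEC63 at 3.92. At mitochondria, 60 of 76 matrix and inner membrane proteins with a presequence were higher, as were 24 of 30 carriers, 13 of 32 outer membrane proteins, 35 of 69 mitochondrial ribosomal proteins and 10 of 26 import receptors and translocases. HEM25, a carrier, had −3.74, MRPL3 −4.41 and TIM44 −4.34. Tail-anchored proteins (0 of 29), cytosolic ribosomal proteins (0 of 138), glycolysis (0 of 21) and translation factors (0 of 35) had no member past the threshold by edgeR. SRP and its receptor had 1 of 8 higher at the ER, the GET and SND pathways 1 of 9 and the peroxisomal list 1 of 39. The Hsf1 list had 5 of 30 higher at mitochondria.

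In all, 501 genes were higher at ER baits and 571 at mitochondrial baits (edgeR, adjusted p below 0.05). Centring each pair on glycolysis and translation factor genes left 149 and 485 genes. In fits without the Ubc6, the Tom20 or the Om45 series, only 8, 0 and 8 genes were called higher at the ER. The count of 1072 fell to 466 without the Ubc6 series, to 221 without the Tom20 series and to 316 without the Om45 series. It went up to 1447 without the Sec63 series without cycloheximide (889 higher at the ER and 558 at mitochondria), to 1258 without the Sec63 series with it (656 and 602), to 1464 with DESeq2 (797 and 667) and to 1374 with library totals (748 and 626).

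**Figure D1:**
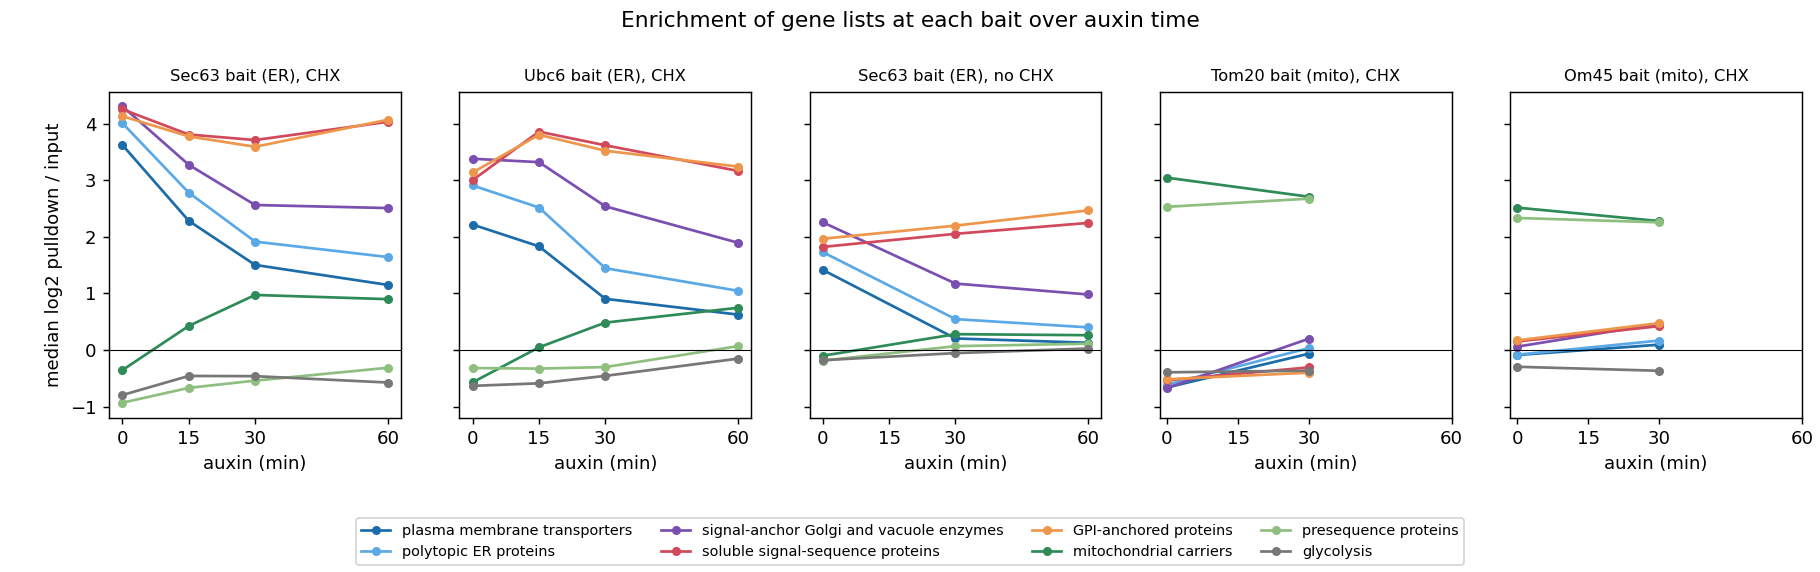
Median log2 enrichment (pulldown over input, vertical axis) of gene lists over auxin time (horizontal axis), with 1 panel per series and 1 colour per list. In the comparison of both compartments at 0 min the polytopic ER list had a median of 3.27 and the carrier list −2.81.

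The changes of ER enrichment asked which messages lost contact with the ER as SRP was depleted. After 15 min, measured in the Sec63 and Ubc6 series with cycloheximide, edgeR called 0 genes, with 885 genes at an unadjusted p under 0.05, and DESeq2 called 146. The genes with the smallest p were GMC1 (−1.81 ± 0.27, SE), HOL1 (−1.60 ± 0.25), SPG5 (1.24 ± 0.19), CCC1 (1.04 ± 0.17) and TMN3 (−1.17 ± 0.19), each with an adjusted p of 0.0622 from edgeR. Of the fixed examples, PHO8 had −0.66 ± 0.25 (adjusted p = 0.235), DAP2 −0.21 ± 0.25 and KAR2 0.29 ± 0.29. The median was −0.77 over 78 plasma membrane transporters and −0.63 over 93 polytopic ER proteins, and 34 and 46 of their members fell when adjusted over the list alone. The 2 series differed in size: list medians in the Sec63 and Ubc6 series were −1.36 and −0.44 for transporters, −1.11 and −0.33 for polytopic ER proteins and −0.90 and 0.05 for single-pass proteins, and DAP2 had −0.88 and 0.60. By camera the transporters had an adjusted p of 5.5e-23, and adjusted p = 0.331 with an estimated correlation. Leaving out the Sec63 series without cycloheximide, which has no 15 min sample but enters the estimate of the spread, gave 326 genes (91 higher and 235 lower), and library totals gave 24 higher and 38 lower.

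After 30 min, membrane proteins had lost ER enrichment in each of the 3 ER series. TCB1, which tethers the ER to the plasma membrane (YOR086C, chromosome XV, 483219 to 486779), fell by 2.79 ± 0.23 log2 units (SE, n = 3; edgeR adjusted p = 5.5e-05). The glucose sensor RGT2 fell by 2.57 ± 0.33 (adjusted p = 0.00027), the vacuolar phosphatase PHO8 (YDR481C, chromosome IV, 1418550 to 1420250) by 2.01 ± 0.22 (adjusted p = 0.000132) and DAP2 (YHR028C, chromosome VIII, 164978 to 167434) by 1.52 ± 0.22 (adjusted p = 0.000472). Most of the fixed examples with a cleaved signal sequence did not pass, and several went both ways over the series. KAR2 (YJL034W, chromosome X, 381327 to 383375) had 0.00 ± 0.25 (adjusted p = 0.997), SUC2 0.28 ± 0.16 (adjusted p = 0.261), GAS1, a GPI-anchored glucanosyltransferase, 0.41 ± 0.24 (adjusted p = 0.261) and PDI1 0.53 ± 0.24 (adjusted p = 0.16). PRC1 rose by 0.58 ± 0.18 (adjusted p = 0.0457). Over the series KAR2 ran from −0.56 to 0.75, PDI1 from −0.29 to 0.99, GAS1 from −0.16 to 0.70 and PRC1 from −0.03 to 1.00, with the lowest value in each case in the Sec63 series with cycloheximide, whereas SUC2 ran from 0.04 to 0.57.

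Of 78 plasma membrane transporters 60 fell and 0 rose (median −1.55), of 93 polytopic ER proteins 77 fell and 0 rose (median −1.41), and of 34 single-pass signal-anchor glycosyltransferases and proteases 26 fell and 0 rose (median −1.15). Adjusted over the list alone, 68, 82 and 28 fell and 0, 1 and 0 rose. Examples were HRD1 (−2.10), a ubiquitin ligase of the ER, HOC1 (−2.04), a mannosyltransferase, SEC63 (−1.95) and SEC61 (−1.63). The translocon list had 5 of 9 lower (median −0.87) and the GET and SND list 4 of 9, with SND3 at −1.47 and GET2 at −1.45, a list whose median (−0.03) stood nearer 0 than its mean (−0.53) and turned positive with library totals (0.28). Of 36 soluble proteins with a signal sequence 3 rose, 3 fell and 30 did not pass (median 0.28), and of 36 GPI-anchored proteins 3 rose, 2 fell and 31 did not pass (median 0.23). BAR1 (−0.96 ± 0.18, edgeR adjusted p = 0.00242), SCJ1 (−0.68) and NPC2 (−0.65) were the soluble proteins that fell. Of the GPI-anchored list YPS7 (−1.53) and PGA1 (−1.10) fell, and TIP1 (0.78) was one that rose. PGA1 is a subunit of a GPI-synthesis enzyme and not itself a GPI-anchored protein. Adjusted over the list alone, 1 rose and 3 fell among soluble proteins, and 3 rose and 2 fell among GPI-anchored proteins. The 72 soluble and GPI-anchored messages together had a mean of series medians of 0.18 ± 0.46 (SD, n = 3), against −1.40 ± 0.46 over the 205 messages of the 3 membrane lists, a difference of 1.58 ± 0.13. Their separation passed camera also with an estimated correlation (unadjusted p = 0.0162). Some members of the polytopic list have a cleaved signal sequence too, so this contrast is one of lists and not of signal types.

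Unfolded protein response genes had 16 of 31 lower and 0 higher (adjusted over the list alone 18 lower, median −0.69). Peroxisomal proteins, some of which are inserted at the ER, had 9 of 39 lower and 2 higher, and PEX28 (−2.00) and PEX31 (−1.94) were among those that fell. Their median of −0.04 became 0.26 with library totals. Tail-anchored proteins, which insert after translation, had 0 of 29 past the threshold by edgeR (median 0.10, and −0.04 or −0.06 when pairs were centred).

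Some messages of mitochondrial proteins rose in ER enrichment, in shares that differed by list, while 468 of all 5286 genes rose. Carriers had 12 of 30 higher and 0 lower (median 0.74, adjusted over the list alone 12 higher), with YMC2 at 2.25 ± 0.40 (SE, n = 3; edgeR adjusted p = 0.00184), CTP1 at 1.57 and ODC2 at 1.45. Import receptors and translocases had 12 of 26 higher (median 0.51), among them PAM16 (2.20) and TOM71 (1.47), mitochondrial ribosomal proteins 16 of 69 (median 0.32) with MRPL11 at 1.91, outer membrane proteins 9 of 32 (median 0.29) and presequence proteins 8 of 76 (median 0.22) with TUF1 at 1.43. Adjusted over the list alone, 15, 21, 9 and 4 of these rose. Among the genes called that changed the same way in every series, COI1, an inner membrane protein, rose most (2.64 ± 0.61). It rose by 4.48 and 4.19 in the Sec63 and Ubc6 series with cycloheximide and by 0.73 in that without. DID4 (YKL002W, chromosome XI, 437778 to 438544), a subunit of the endosomal sorting complex, rose by 2.03 ± 0.15 (adjusted p = 3.93e-05).

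In all, 608 genes fell and 468 rose after 30 min, and 505 of those that fell and 130 of those that rose changed more than 2-fold. The median over all genes was 0.15, and the number that rose depended on the scaling while the number that fell did so less: 190 rose and 646 fell with pairs centred on glycolysis and translation factor genes, 210 and 651 with pairs centred on their median, and 1603 and 550 with library totals. Cytosolic lists moved with that shift, with 6 of 138 ribosomal proteins higher (1 with either centring, 59 with library totals, and a median that turned from 0.15 to −0.02 with the glycolysis centring), 4 of 21 glycolysis genes, 7 of 63 ribosome biogenesis genes and 5 of 30 chromatin genes. Without the series block 80 genes passed (42 rose and 38 fell). Without the Sec63 series with cycloheximide 516 passed (66 and 450), and without the Ubc6 series 650 (131 and 519). Without the Sec63 series that had no cycloheximide, 1080 passed (441 and 639). Without the Tom20 or the Om45 series, which hold no ER pair, 197 and 198 rose and 607 fell in each fit. TMM against the Tom20 pulldown at 30 min gave 322 and 626. The rises thus depended on the libraries in the fit and on the scaling more than the falls, and not only on single ER series.

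**Figure D2:**
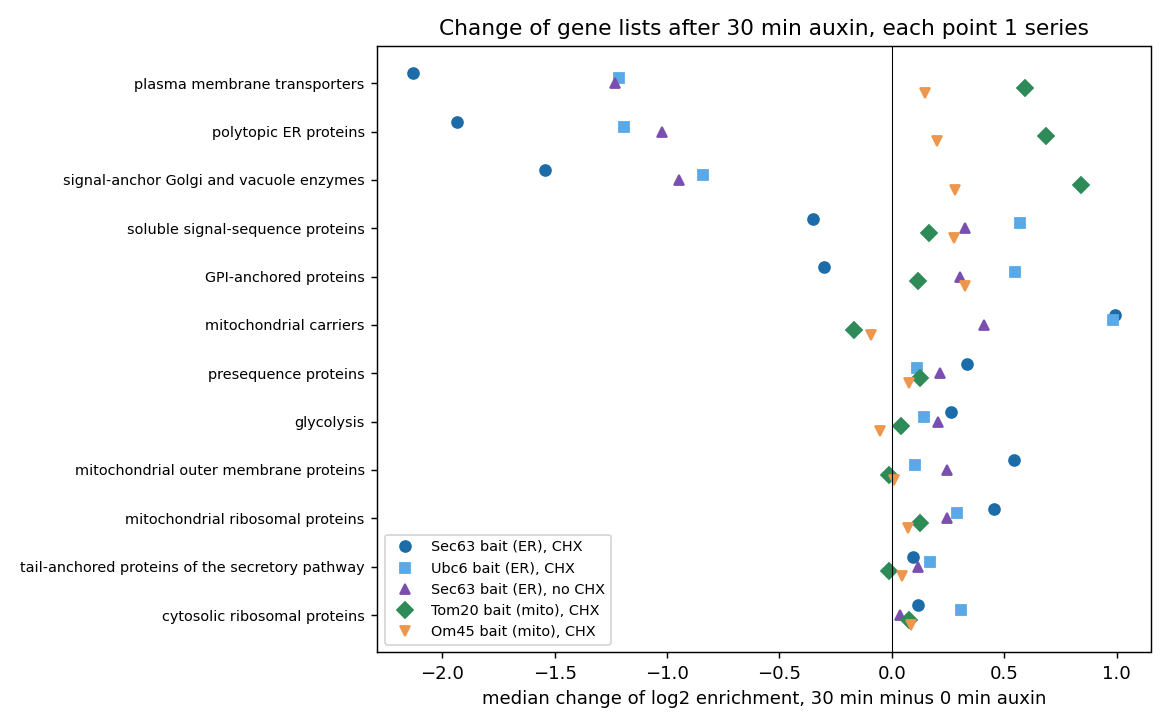
Median change of log2 enrichment after 30 min auxin (horizontal axis) for each gene list (vertical axis), with 1 point per series and a separate colour and symbol for each series. Plasma membrane transporters averaged −1.53 over the ER series and 0.37 over the mitochondrial series, and carriers 0.80 and −0.13.

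After 60 min membrane proteins were again lower, and the change from 30 to 60 min was not tested. TCB1 fell by 3.28 ± 0.23 (SE, n = 3; edgeR adjusted p = 8.58e-06), GPI13, an enzyme of GPI synthesis, by 2.58 ± 0.14 (adjusted p = 1.6e-06), PHO8 by 2.43 ± 0.22 (adjusted p = 2.2e-05) and DAP2 by 2.09 ± 0.22 (adjusted p = 3.94e-05). KAR2 had 0.03 ± 0.25 (adjusted p = 0.935), GAS1 0.33 ± 0.24 (adjusted p = 0.283) and PDI1 0.54 ± 0.24 (adjusted p = 0.101), while PRC1 rose by 0.74 ± 0.18 (adjusted p = 0.00991) and SUC2 by 0.53 ± 0.16 (adjusted p = 0.0249). Of 78 transporters 65 fell (median −1.68), of 93 polytopic ER proteins 81 fell and 2 rose (median −1.65), of 34 single-pass proteins 28 fell (median −1.42) and of 9 translocon genes 5 fell and 1 rose. Adjusted over the list alone, 69, 82, 31 and 5 fell and 0, 2, 0 and 2 rose. Soluble proteins had 5 rises and 5 falls among 36 (median 0.20, and −0.08 or −0.09 with centred pairs), and GPI-anchored proteins 9 rises and 2 falls (median 0.40). The 72 soluble and GPI-anchored messages stood 1.95 ± 0.17 log2 units (SD, n = 3) above the 205 membrane messages, compared with 0.97 ± 0.18 (n = 2) after 15 min.

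The number of rises after 60 min depended on the settings. The counts were 1220 higher and 649 lower, with an all-gene median of 0.29, but 516 higher and 673 lower when TMM took the Tom20 pulldown at 30 min as its reference, 216 and 710 with pairs centred on glycolysis and translation factor genes, and 341 and 763 with DESeq2, which changes the scaling together with the model and test. Cytosolic ribosomal proteins had 93 of 138 higher, and 16, 1 and 2 of 138 under those alternatives. Carriers had 15 of 30 higher, import components 18 of 26, mitochondrial ribosomal proteins 38 of 69 and presequence proteins 38 of 76, and with pairs centred on glycolysis and translation factor genes these counts were 9, 8, 12 and 6. DID4 (2.71 ± 0.15, adjusted p = 1.6e-06) and TUF1 (1.91 ± 0.19, adjusted p = 3.21e-05) were among the genes that rose. The count of 1869 was 628 without the Sec63 series with cycloheximide, where 64 genes were higher, 564 were lower and 171 of the 1869 genes had the opposite sign. It was 719 without the Ubc6 series, and 933 without the Tom20 or the Om45 series.

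The ER set defined in the Ubc6 pair at 0 min held 1071 genes. The input of that pair was the smallest library (2.04 M counts), so genes with few counts could enter the set by noise. Its median change in the Sec63 series with cycloheximide was −0.92 after 15 min, −1.49 after 30 min and −1.63 after 60 min, and without cycloheximide −0.64 after 30 min and −0.65 after 60 min. Other genes had medians of 0.18 to 0.37. The share of members below 0 was 86.8% after 30 min and 81.6% after 60 min with cycloheximide, and 72.2% and 69.1% without. In an edgeR fit without the Ubc6 series, which defined the set, 516 members fell and 7 rose after 30 min, and 551 fell and 13 rose after 60 min. In that fit the falls of the set had unadjusted p-values of 0.0474 and 0.0433 by camera with an estimated correlation (1071 genes). The 25 lists were held to p-values adjusted over the lists, and with an estimated correlation none passed in any comparison. Their lowest adjusted p by camera was 0.0507, so the set and the lists were held to unlike thresholds.

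The mitochondrial series asked whether messages that need SRP moved to the mitochondrial surface. After 30 min auxin, some secretory messages rose there. ERG5, a sterol desaturase of the ER (YMR015C, chromosome XIII, 300869 to 302485), rose by 2.72 ± 0.23 (SE, n = 2; edgeR adjusted p = 0.000407), the biotin transporter VHT1 by 2.39 ± 0.30 (adjusted p = 0.00202) and the pheromone exporter STE6 by 2.34 ± 0.24 (adjusted p = 0.00105). The ER folding enzyme CPR5 (1.88), the potassium transporter TRK1 (1.73) and the mannosyltransferase MNN1 (1.21) also rose, so that the genes that rose included soluble and single-pass proteins. OLE1, the fatty acid desaturase (YGL055W, chromosome VII, 398628 to 400160), had 2.82 ± 0.30 (adjusted p = 0.00105), but its input footprints changed by −2.60 and −2.66 in the same series, so its enrichment rose mainly as the input fell. Input footprints of MNN1 changed by −1.28 and −1.30, so its enrichment too rose mainly as the input fell, and those of ERG5 by −0.04 and −0.30. The other single-pass proteins that rose, MNN5 (1.53) and OCH1 (1.51), had mean input changes of −1.48 and −0.62. That of CPR5 was 0.37. KAR2 did not pass at 1.37 ± 0.30 (adjusted p = 0.0583), and PHO8 and DAP2 had 0.22 ± 0.26 each.

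In the mitochondrial series 49 genes rose and 6 fell. Polytopic ER proteins had 9 of 93 higher (median 0.43), transporters 5 of 78 (median 0.37), single-pass proteins 3 of 34 (median 0.51), soluble proteins 2 of 36 (median 0.24), unfolded protein response genes 3 of 31 and GPI-anchored proteins 0 of 36 (median 0.26). Adjusted over the list alone, 23, 9, 13, 5, 7 and 0 rose. By camera the polytopic list had an adjusted p of 3.58e-28, and adjusted p = 0.499 with an estimated correlation. Of the mitochondrial lists, no member of presequence proteins, carriers (median −0.14), outer membrane proteins, mitochondrial ribosomal proteins or import components passed by edgeR, at 345 genes with an unadjusted p under 0.05. Among genes that fell were COX20 (−1.16), an assembly factor of cytochrome oxidase, and HSP26 (−1.07), the 1 Hsf1 gene of 30 that passed, whose input footprints rose by 6.51 and 3.07 in the same series. An ER set of 959 genes, defined over the 3 ER pairs, had a median change of 0.50 in the Tom20 series and 0.20 in the Om45 series, against 0.03 and 0.04 over other genes, and 48 members rose and 1 fell. With an estimated correlation that set did not pass camera (p = 0.13 over 959 genes). The 55 calls were 0 without the Tom20 series, 26 without the Om45 series and 17 without the Ubc6 series. They were 0 without the series block, 141 with DESeq2 and 210 when the mitochondrial series were fitted alone.

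Testing the difference of both 30 min changes asked whether the compartments responded differently. Of 5286 genes, 561 changed more in the upward direction at mitochondria and 137 more in the upward direction at the ER (468 and 271 with library totals). ERG5 differed by 4.52 ± 0.30 (SE; edgeR adjusted p = 2.56e-05), OLE1 by 3.96 ± 0.39 (adjusted p = 0.000142), PHO8 by 2.22 ± 0.34 (adjusted p = 0.00118), DAP2 by 1.74 ± 0.34 (adjusted p = 0.00493) and KAR2 by 1.37 ± 0.39 (adjusted p = 0.0364). The differences were positive for 58 of 78 transporters (median 2.03), 75 of 93 polytopic ER proteins (median 1.88), 31 of 34 single-pass proteins (median 1.67) and 17 of 31 unfolded protein response genes, and adjusted over the list alone for 65, 85, 33 and 21. Carriers went the other way, with 7 of 30 lower and 0 higher (median −0.89, adjusted over the list alone 12 lower and 1 higher), among them YMC2 (−2.58), PET8 (−1.97) and ODC2 (−1.69). COX20 had −2.88 ± 0.26 (adjusted p = 8.38e-05). Without the series block 4 genes passed (3 positive and 1 negative). Without the Tom20 series 236 passed (218 and 18), and without the Sec63 series with cycloheximide 429 (374 and 55). Without the Sec63 series that had no cycloheximide, 807 passed (612 and 195).

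**Figure D3:**
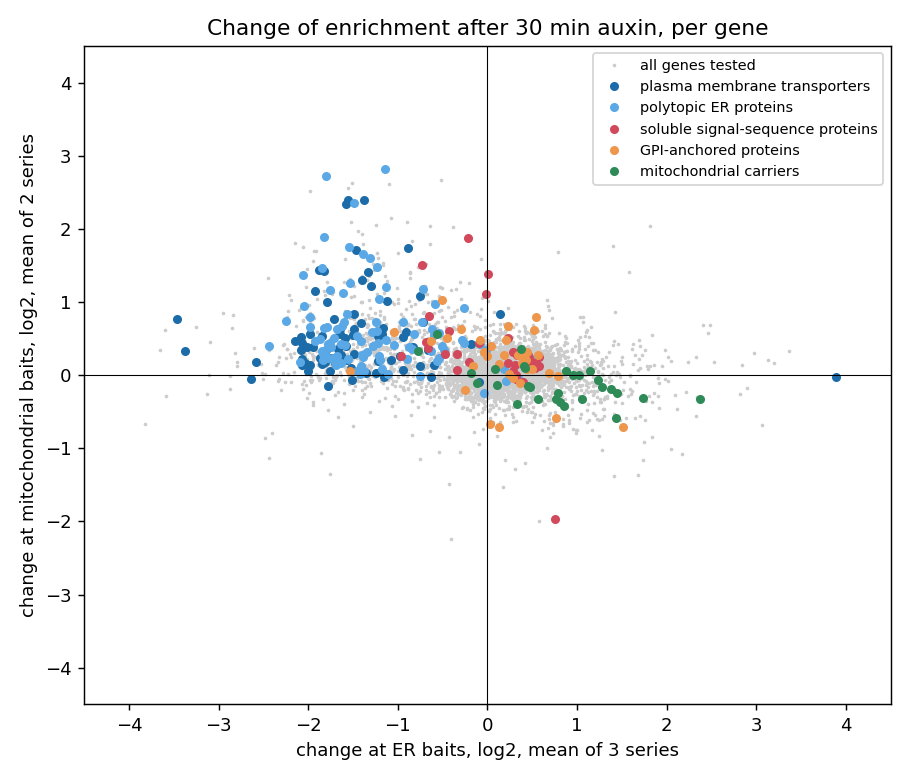
Change of log2 enrichment after 30 min auxin at ER baits (horizontal axis) against that at mitochondrial baits (vertical axis) for 5286 genes, with 1 point per gene, lists in colour and 1 gene outside the axes. Transporters and polytopic ER proteins lie to the left (medians −1.55 and −1.41) and slightly above 0 (0.37 and 0.43), and carriers to the right (0.74).

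The comparison of both ER baits asked whether the neighbourhood of the translocon and the wider ER surface met different messages, over 4 matched times with cycloheximide. Transporters and polytopic ER proteins were enriched more with the Sec63 bait in the fit over all times. PDR15, a multidrug transporter (YDR406W, chromosome IV, 1279210 to 1283799), was 1.89 ± 0.23 log2 units (SE, n = 4) higher (edgeR adjusted p = 0.00336), the siderophore transporter ARN1 1.51 ± 0.14 (adjusted p = 0.000283) and SEC61 0.91 ± 0.17 (adjusted p = 0.0107). Polytopic ER proteins had 53 of 93 higher (median 0.70), transporters 36 of 78 (median 0.80), single-pass proteins 6 of 34, soluble proteins 5 of 36 and GPI-anchored proteins 4 of 36, with 83, 57, 15, 21 and 6 adjusted over the list alone. Among the genes higher with the Ubc6 bait, the kinase SCH9 (YHR205W, chromosome VIII, 509363 to 511837) had −3.55 ± 0.14 (adjusted p = 8.59e-07), the lipid kinase FAB1 −2.85 ± 0.21 (adjusted p = 5.88e-05), the retromer subunit VPS35 −2.55 ± 0.13 (adjusted p = 6.29e-06) and the ubiquitin ligase RSP5 −2.20 ± 0.14 (adjusted p = 2.18e-05). Presequence proteins had 17 of 76 higher with Ubc6 and 1 with Sec63 (median −0.29), with TIM44 at −0.82, while carriers had 6 of 30 higher with Sec63 (median 0.43). Peroxisomal proteins had 6 of 39 higher with Sec63, PEX22 by 1.29.

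With the Sec63 bait 430 genes were higher and 86 lower (186 and 220 with library totals). The count of 516 was 76 without the 15 min pairs (41 higher and 35 lower), 265 without the 30 min pairs (215 and 50) and 38 without the 60 min pairs (6 and 32), so most genes higher with Sec63 were called only with the 15 and 60 min pairs in the fit. The medians of polytopic ER proteins (0.22 to 1.08) and of transporters (0.461 to 1.405) were above 0 at each of the 4 times, while those of soluble proteins ran from −0.02 to 0.97. The Ubc6 libraries differ from the others also in carrying no barcode.

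Cycloheximide was compared with none in the Sec63 series at 3 matched times, where the length of the biotin pulse differs together with the drug. Messages of soluble, GPI-anchored, single-pass and polytopic secretory proteins were more enriched with cycloheximide. The cell-wall protein TIR3 (YIL011W, chromosome IX, 333727 to 334536) was 3.32 ± 0.25 log2 units (SE, n = 3) higher (edgeR adjusted p = 0.00146), CWP1 3.07 ± 0.12 (adjusted p = 0.00105) and the transport receptor ERV25 2.99 ± 0.12 (adjusted p = 0.00105). PDI1 was higher by 2.17 ± 0.29 (adjusted p = 0.0051), DAP2 by 1.72 ± 0.13 (adjusted p = 0.00148) and KAR2 by 1.63 ± 0.17 (adjusted p = 0.00257). Of SRP and its receptor, 2 of 8 were higher, both of them receptor subunits, and the particle's SRP21 was lower (−0.79). Of the lists, 32 of 36 soluble proteins, 30 of 36 GPI-anchored proteins, 33 of 34 single-pass proteins, 65 of 78 transporters, 83 of 93 polytopic ER proteins and 24 of 31 unfolded protein response genes were higher, with 34, 32, 33, 74, 87 and 27 adjusted over the list alone. The import stress and Pdr1/Pdr3 list had 8 of 16 higher and peroxisomal proteins 13 of 39 (median 0.68, but −0.12 with library totals). Among the genes that were lower were NPL3 (−1.07), UBI4 (−0.94) and ATP1 (−0.73). Presequence proteins had 23 of 76 lower and 2 higher (median −0.37). Cytosolic ribosomal proteins had 35 of 138 lower (median −0.33), translation factors 11 of 35, tail-anchored proteins 5 of 29 and Hsf1 genes 6 of 30, but the medians of the ribosomal, tail-anchored and Hsf1 lists turned to 0.03, 0.02 and 0.02 with pairs centred on glycolysis and translation factor genes. The counts were 1013 higher and 340 lower, 1559 and 16 with that centring, 1047 and 178 with pairs centred on their median, and 731 and 3032 with library totals, where the all-gene median was −0.80. The count of 1353 was 2437 without the 0 min pairs (1419 higher and 1018 lower). It was 821 without the 30 min pairs (775 and 46) and 674 without the 60 min pairs (673 and 1). Most genes called lower thus depended on the 30 and 60 min pairs.

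Whole-cell inputs asked how translation changed during auxin treatment, with 5 series at 30 min and 3 at 60 min. No auxin-treated series without the degron was analysed here, so effects of auxin itself cannot be told apart from those of SRP loss. Hsf1 heat-shock and proteasome genes rose and ribosome biogenesis genes fell. The Hsp70 gene SSA4 (YER103W, chromosome V, 364589 to 366517) rose by 6.46 ± 0.75 log2 units (SE, n = 5; edgeR adjusted p = 2.39e-05), the disaggregase HSP104 by 3.89 ± 0.21 (adjusted p = 5.83e-08), HSP42 by 4.47 ± 0.27 (adjusted p = 1.24e-07) and RPN4, the transcription factor of proteasome genes, by 2.17 ± 0.13 (adjusted p = 9.25e-08). KAR2, which Hsf1 also drives, rose by 1.56 ± 0.19 (adjusted p = 3.9e-05). The export pump PDR12 rose by 4.53 ± 0.45 (adjusted p = 8.06e-06). The desaturase OLE1 fell by 2.94 ± 0.16 (adjusted p = 6.74e-08) and the nucleolar protein NSR1 by 2.55 ± 0.18 (adjusted p = 4.25e-07). After 60 min HSP26 had risen by 5.74 ± 0.57 (n = 3; adjusted p = 2.84e-06) and the helicase DBP2 had fallen by 4.59 ± 0.21 (adjusted p = 3.59e-08). The drug exporter FLR1 rose by 7.31 ± 1.38 (adjusted p = 0.000582), with a spread of 4.72 over series (SD).

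All 30 Hsf1 genes and all 35 proteasome genes rose at both times, with medians of 2.43 and 0.77 after 30 min and 2.56 and 1.12 after 60 min. General stress genes had 27 and 31 of 36 higher, with medians of 0.86 and 1.54. All 63 ribosome biogenesis genes fell, with medians of −1.16 and −1.90. Cytosolic ribosomal proteins had 43 of 138 lower and 1 higher after 30 min (median −0.23) and 132 lower and 1 higher after 60 min (median −1.39), while adjusted over the list alone 27 and 134 fell. Without RPP1, a subunit of RNase P that the list took in by its name, 42 and 131 of 137 fell, and 24 and 133 adjusted over the list alone. Translation factors had 21 and 31 of 35 lower, among them YEF3 (−0.85 and −2.84), and chromatin genes 19 and 22 of 30. By camera the Hsf1 list had an adjusted p of 1.34e-66 after 30 min, and adjusted p = 0.0507 with an estimated correlation. Unfolded protein response genes were mixed, with 6 higher and 11 lower of 31 after 30 min and 7 and 10 after 60 min (medians −0.12 and 0.02). The oxidase ERO1 rose by 2.38 after 30 min. HAC1, the transcription factor of that response, fell by 2.08 ± 0.64 (SE; edgeR adjusted p = 0.0189). It had a mean input count of only 42.1, and its series ran from −3.92 to −0.84.

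Polytopic ER proteins had 50 lower and 8 higher after 30 min and 49 and 11 after 60 min, and single-pass proteins 22 and 18 of 34 lower. Transporters were split (15 higher and 26 lower, then 23 and 26), as were soluble proteins (8 and 11, then 14 and 12), GPI-anchored proteins (3 and 11, then 8 and 15) and carriers (5 and 9, then 6 and 12). Outer membrane proteins had 12 and 14 of 32 higher, the import stress and Pdr1/Pdr3 list 7 and 10 of 16 and glycolysis 9 and 7 of 21. Peroxisomal proteins had 7 and 13 of 39 higher and tail-anchored proteins 7 and 8 of 29. The tail-anchored median was near 0 and changed sign with library totals. The footprints of SRP72 itself fell by 0.32 and 0.52. These footprints do not measure the depletion, which acts on the protein. In all, 1150 genes rose and 1265 fell after 30 min (644 and 1779 with library totals), and 1616 rose and 1489 fell after 60 min.

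**Figure D4:**
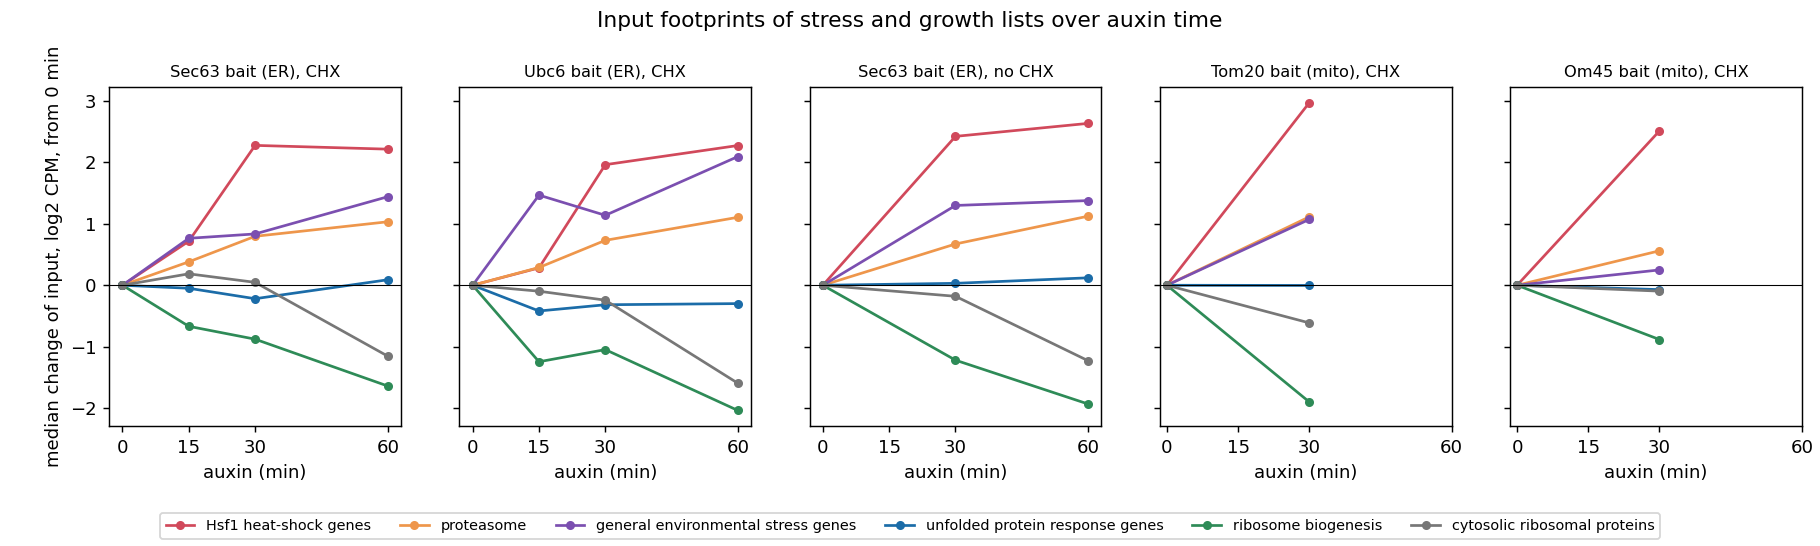
Median log2 change of input footprints (vertical axis) of gene lists relative to 0 min over auxin time (horizontal axis), with 1 panel per series and 1 colour per list. Hsf1 genes averaged 2.43 over 5 series after 30 min and ribosome biogenesis genes −1.18.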

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

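Of the tests in this part, those of scaling for the carriers and for the ER set, that of input changes for the ER set, that of baits reaching the ER, all tests by other splits of the libraries and the spread required of the cytosolic test were chosen only after the results were seen. A test of the carriers against presequence messages was seen first (0.57 ± 0.35, above 0 in 3 of 3 series) and replaced by the test on input changes.

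The response to 30 min auxin differed between ER and mitochondrial baits by the test of the difference itself. The difference, mitochondrion minus ER, was positive for 561 genes and negative for 137. It was positive for 58 transporters, 75 polytopic ER proteins and 31 single-pass signal-anchor proteins, and negative for 7 carriers. For transporters and polytopic ER proteins most of the difference was the fall at the ER (medians −1.55 and −1.41, against 0.37 and 0.43 at mitochondria). A signal outside the listed genes was found in the Ubc6 input at 0 min, where 42.3% of the total behind the RPKM values (3.54 M, of which 2.04 M was in listed genes) lay outside them, against 0.474% to 4.31% in the other 4 inputs at 0 min. All 8 Ubc6 libraries were raised, with 8.32% to 42.3% in inputs and 4.501% to 18.9% in pulldowns, against 0.234% to 4.31% in the 22 libraries of the other series. The source was not tested.

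The median of the ER set rose in mitochondrial enrichment after 30 min, by 0.50 in the Tom20 series and 0.20 in the Om45 series. Scaling of the pulldown libraries moves all genes alike, and the set exceeded other genes by 0.31 ± 0.22 (SD, n = 2), which argues against scaling as the whole cause. The set exceeded the 10 other genes nearest in input change by 0.30 ± 0.24 (above 0 in both series), which argues against input changes as the whole cause, though for single genes such as OLE1 the fall of the input (−2.63) was nearly as large as the rise in enrichment (2.82). If messages were released into the cytosol, the share of the set above the 95th percentile of cytosolic lists would rise by at most 5 points. It rose by 29.1 in the Tom20 series (8.97% to 38.1%) and by 5.21 in the Om45 series (73.2% to 78.4%). In the Om45 series most of the set stood above that percentile before auxin, so less room for a rise was left. There, messages that joined the cytosolic distribution would lower the share. Both rises passed the limit of 5 points, that in the Om45 series only just. The mean of 17.2 does not exceed 5 by more than its spread of 16.9 (SD), so release stays open. If the mitochondrial baits reached the ER, soluble and GPI-anchored messages, which fell less at the ER, would gain at least as much as membrane messages, but the difference of −0.22 ± 0.44 had opposite signs in the series (−0.54 and 0.09). If messages that left the ER moved to mitochondria, larger losses would go with larger gains, but the Spearman correlation across genes was 0.016 on average (−0.141 and 0.173), so redirection, release and bait position cannot be told apart here.

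The median of carrier messages rose at the ER, with 12 of 30 past the threshold, while none of the carriers rose at mitochondria by edgeR. Their median exceeded that of glycolysis and translation factor genes by 0.62 ± 0.32 (SD, 3 of 3 series), that of the 10 genes nearest in baseline ER enrichment by 0.70 ± 0.45, and that of the 10 genes nearest in input change by 0.68 ± 0.37. In the same order, the excess was 0.77, 1.09 and 0.81 in the Sec63 series with cycloheximide and 0.84, 0.78 and 0.97 in the Ubc6 series. In the Sec63 series without cycloheximide it was smaller, at 0.25, 0.21 and 0.25. These values, above 0 in each series, argue against scaling, a low baseline and translation changes as the whole cause. What brings them there was not tested. An effect of auxin or of the stress response was not tested, as no treated series without the degron was analysed here.

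The ER change of soluble and GPI-anchored messages after 30 min (0.18 ± 0.46, SD) stood above that of membrane messages, with members going both ways. The difference of 1.58 remained 1.37 ± 0.23 (SD, n = 3) against the 10 membrane messages nearest in baseline enrichment, 1.49 ± 0.21 against those nearest in gene length and 1.51 ± 0.10 against those nearest in input change, which argues against each as the whole cause. The median gene length was 1363.5 against 1677 bases and the median baseline 2.78 against 2.70. Targeting routes were not tested, as signal classes were not derived from sequence.

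Other splits of the libraries were counted for each comparison of at least 3 samples per group. For the ER change after 30 min the real split gave 656 genes and the highest of the other splits 0; after 60 min 786 and 0; for cycloheximide 1353 and 0; for the inputs after 60 min 2346 and 0. In each of these only 1 split, the real one, gave as many, and 10 splits are too few for a share under 0.05. For the inputs after 30 min the real split gave 2187 genes and the highest other of 100 drawn gave 1. Those splits mix series, and the 16 splits that part the times within each series, of which the highest other gave 0, are too few for a share under 0.05. For the bait the real split gave 516 genes with auxin time as a block, and the highest other of 32 splits gave 317. The 8 splits that part the baits within each time, of which the highest other gave 0, are too few as well. Without that block the real split gave 23 genes, 2 of 35 splits gave as many, and the highest gave 424. That split set 0 and 15 min against 30 and 60 min, so it follows the structure that auxin time gives the samples.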

How the results depend on the processing

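The alternatives of centring on each pair's median, library totals for inputs, TMM against another reference library and lists without misplaced genes were tests chosen only after the results were seen. Directions of the ER set held under all alternatives run: −1.06 at main settings after 30 min (−1.49 to −0.64 leaving out a series), −1.14 after 60 min (−1.63 to −0.65) and 0.35 at mitochondria (0.20 to 0.50). Total input counts stayed within 1.5 times under all alternatives, but rises after 30 min went from 1150 to 644 with library totals and 761 without the series block. Values of named genes kept direction and side of the threshold in 918 of 1092 alternatives for the ER change after 30 min (168 weaker, 6 stronger). They did so in 928 of 1148 after 60 min, 423 of 516 at mitochondria, 650 of 770 without auxin, 587 of 724 for the bait and 620 of 728 for cycloheximide. Most of these genes were named because they passed with large changes in the same data, so the shares do not describe all genes called. Reversals of named genes, all with library totals in the cycloheximide comparison, were MRPL25 (−0.13), PAM17 (−0.25), TDH1 (−0.14) and EFT2 (−0.0193). That scaling moves the median of all genes there to −0.80 and turns 76 called genes. Of genes called after 60 min, 171 turned without the Sec63 series with cycloheximide, 11 with glycolysis and 2 with median centring, and of inputs after 60 min 7 without the series block.

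Counts moved as follows. For baits without auxin (1072 genes), 634 passed with glycolysis centring, and 221 to 1447 when leaving out a series. For 15 min (0 genes), library totals gave 62, DESeq2 146, and leaving out a series 0 to 326. For 30 min (1076), library totals gave 2153, no series block 80, and leaving out a series 516 to 1080. For 60 min (1869), no filter gave 1179, a mean input of at least 50 gave 1184, and TMM against the Tom20 pulldown at 30 min gave 1189 on the same genes, so the change of reference library accounts for the effect of both filters. Glycolysis centring gave 926, median centring 944, DESeq2 1104, no block 401, the ER series alone 930, and leaving out a series 628 to 1655. For mitochondria (55), library totals gave 87, DESeq2 141, no block 0, the mitochondrial series alone 210, and leaving out a series 0 to 47. For the difference (698), no block gave 4 and leaving out a series 236 to 807. For the bait (516), leaving out a time gave 38 to 642. For cycloheximide (1353), library totals gave 3763 and leaving out a time 674 to 2437. Apart from the filters, the cause was not tested. Genes under a mean input count of 20 were not tested, and the smallest library held 2.04 M counts. Targeting-signal classes and their alternatives were not run.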

Other observations

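After 15 min, inputs were read in 2 series. The weak-acid pump PDR12 rose by 4.86 ± 0.52 log2 units (SE, n = 2; edgeR adjusted p = 0.000456), the ammonia exporter ATO2 by 4.18 ± 0.23 (adjusted p = 7.97e-07), HSP42 by 2.13 ± 0.32 (adjusted p = 0.00135) and the catalase CTT1 by 2.01 ± 0.37 (adjusted p = 0.00431). NSR1 fell by 2.80 ± 0.27 (adjusted p = 0.000232) and DBP2 by 1.84 ± 0.22 (adjusted p = 0.000601). Of 63 ribosome biogenesis genes 53 fell (60 adjusted over the list alone), of 36 general stress genes 18 rose (25) and of 30 Hsf1 genes 15 rose (23). In all 277 genes rose and 448 fell. The ER change at that time had 0 calls by edgeR, 885 genes at an unadjusted p under 0.05 and 146 calls by DESeq2. This comparison was not among those planned, and the order of input and ER changes was not tested. Effects of auxin itself cannot be told apart from those of SRP loss at this time either.

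Footprints of marker genes were read as a check of the labels. MET17, also called MET15, had 0 counts in the inputs of 3 of the S288C series and 1 in the Sec63 series without cycloheximide, but 943 to 1361 counts per 1e6 in the Tom20 series, whose strain is W303. HIS3 had 2 counts over the 4 Ubc6 inputs. ADE2 was at 5.21 to 7.98 counts per 1e6 in the Tom20 inputs and at 114 or more in the others. URA3 was at 66.9 to 241 in the Ubc6 inputs, although the label lists ura3 as deleted. Tagged genes were lower in their own series at 0 min for SEC63 (129 and 176, against 219 to 259 elsewhere), TOM20 (56.6 against 96.5 to 139) and OM45 (18.6 against 32.0 to 68.4), and higher for UBC6 (124 against 73.3 to 93.7). No pair of libraries had identical counts, and the highest Spearman correlation between libraries was 0.993.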
